A study of Chlamydomonas reinhardtii with 34 samples.

How the data were processed

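The series holds poly-A RNA of the green alga Chlamydomonas reinhardtii, grown with or without copper in Tris-acetate-phosphate medium (TAP), in which acetate is a carbon source, or in minimal medium without acetate. The wild type is strain 2137; crr1-2 is a mutant in CRR1, the transcription factor of the nutritional copper response, and crr1:CRR1 is that mutant carrying the gene again. Of 34 samples, 28 whole-transcriptome samples were used. The other 6, short-tag libraries of 17 nt, were not analysed here.

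Each deposited file has 3 columns and no header: a read start on 1 coordinate that joins the whole genome, an aligned length, and a read count. From the values, the third column holds whole-number counts of reads, deposited without normalization, and each start and length is listed once. Aligned lengths were used only to tell full-length from partial alignments. The aligner, its settings, the treatment of reads with several matches and the genome build are not given in the sources used here. The files name no chromosome, strand or gene. Because the build is not known, no position from the reference table of 17742 genes was applied, and no window could be given a gene name. The planned gene lists and the level of CRR1 itself were therefore not tested. Without strand, overlapping transcripts on opposite strands cannot be told apart.

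Reads were summed in windows of 1000 bases of the joined coordinate, 118215 in all, of which 101670 held at least 1 read. Samples were merged into libraries by a rule fixed before the data were examined. Paired-end samples of a group with the same insert size per the labels were taken as mates and averaged, with rounding to whole counts. Samples of a group with the same read length and library type were summed where chi-square per degree of freedom over windows with 20 or more reads was under 2 in every pair. The 6 mate pairs had values of 0.29 to 0.35, below the sampling noise of independent reads, as mates read the same fragments. The 16 same-format single-end pairs had 1.02 to 1.19, so they differed by about the sampling noise. Pairs of 1 group in different formats or with different inserts had values of 2.82 to 15.79. The crr1-2 and crr1:CRR1 groups hold only 1 such pair each, with nothing else in the group to compare it with, and were merged in the same way. This left 12 libraries: 3 each for wild type in TAP without and with copper (33-nt single-end, 35-nt paired-end and 35-nt single-end), 1 each for crr1-2 and crr1:CRR1 (35-nt single-end), and 2 each for wild type in minimal medium without and with copper (50-nt paired-end). Libraries of a group are called 1, 2 and 3 in that order of formats, and those of minimal medium 1 and 2 in the order of the labels. No label says that samples of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

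The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on window counts, with TMM normalization, filterByExpr on group, and 1 joint fit of all 12 libraries with group and sequencing format as terms. It tested 76755 windows holding 99.63% of the reads, with 4 residual degrees of freedom. A window was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. The medium comparison used group alone, since every minimal-medium library and no other is 50-nt paired-end. A lone crr1-2 or crr1:CRR1 library was assumed to vary like the libraries of the other groups; those comparisons have no replicate check of their own. Called windows of 1 direction with at most 2 other windows between them were joined into a locus. Levels are given in CPM, a library's reads scaled to a common total after TMM, as means over the libraries of a group with the SD. Where a group had 0 reads, a fold is a bound computed with a floor of 3 reads over the group. With 1 to 3 reads it has an exact binomial 95% interval. Intervals and floors cover counting error only. Overlaps of called windows were tested by Fisher's exact test, two-sided, against the windows tested, with Benjamini-Hochberg adjustment over the 14 overlaps computed.

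The naming rule, fixed likewise, took the 8 largest rises and falls per comparison by log2 change, with at least 5 CPM in the higher group and the same direction in each format holding both groups. Its requirement of a gene symbol could not be met. It was applied to loci, ranked by their most changed window, and the text gives the first 2 of each direction, by position. The same rule was applied after the data were seen to the comparison of crr1:CRR1 with wild type and to the difference between media. For the difference, ranking used the difference and direction by format was not required. The limit of 5 CPM was applied there to the wild-type groups in TAP alone. Other loci named were chosen after their values were seen.

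In wild type in TAP, libraries with the same label numbers share a format. Their deviations from the group means correlated at 0.708, 0.441 and 0.314, which a shared format alone could give. Label number and format cannot be told apart there, so the format term is also the block of the numbers. The fits were tested on simulated counts drawn from the windows' real means and dispersions, on 73099 windows after the filter. Of these, 98 were changed 2-fold and 97 or 98 were changed 4-fold per comparison, and 196 and 194 for the difference between media. For copper in TAP, 91.8% of 4-fold and 36.7% of 2-fold changes were recovered, for copper in minimal medium 82.5% and 23.5%, and for crr1-2 against crr1:CRR1 64.3% and 8.16%. For the difference between media, 67% of 4-fold and 10.7% of 2-fold differences were recovered. False calls numbered 5 for each of the first 3 comparisons and 13 for the difference. With so few windows changed, the adjusted p is stricter than where many change, so these rates are not the power of the real tests. A true 2-fold change also lies at the limit of a log2 change of 1, so estimates below it were not called at any p.

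Depth ranged from 3072852 to 11164737 reads per sample and from 5539012 to 14864615 per library. Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, mate 1 only, no minimum fold, fits of the compared groups alone, the replicate block, single-end samples kept separate, a TAP baseline of 1 format, and each library left out. Added after the data were seen were windows of 500 and 5000 bases, each position and length counted once, full-length alignments only, and leaving out the 33-nt libraries. Pairs of TAP libraries were also compared, after the data were seen, by counting windows 2-fold apart with at least 5 CPM in the higher library. Reads were tabulated and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.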

Results

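Transcript abundance was measured genome-wide in 6 groups of Chlamydomonas cultures: wild type without and with copper in TAP, wild type without and with copper in minimal medium, and crr1-2 and crr1:CRR1 without copper in TAP. The 28 samples held 179526596 reads. Wild type in TAP had 8 samples without copper (3072852 to 6353102 reads each) and 8 with copper (3574496 to 5970697). The 2 crr1-2 samples had 5320280 and 5983364 reads, and the 2 crr1:CRR1 samples 5553624 and 6245458. Wild type in minimal medium had 4 samples without copper (9111985 to 11164737) and 4 with copper (10051022 to 10437811). After mates of paired-end libraries, and single-end samples that differed by about the sampling noise, were merged, n was 3 libraries in each wild-type group in TAP, 2 in each wild-type group in minimal medium, and 1 each for crr1-2 and crr1:CRR1. Levels are in CPM, reads scaled to a common library total. Positions are those of the deposited joined coordinate, whose build is not given in the sources used here. An adjusted p given for a locus is the smallest over its called windows, not a test of the whole locus. Under the alternatives it is that of the most changed window. Loci are ranked by their most changed window, and their folds are those of the whole locus. They are named by the first and last base of their windows, since the files pair positions with no gene; the level of CRR1 itself was not looked up for the same reason.

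The first comparison asked which transcripts of the wild type respond to copper deficiency when acetate is supplied. CRR1, a transcription factor, is known to govern much of that response. The response was mostly a rise: 972 windows in 346 loci were higher without copper and 124 windows in 82 loci were lower. By fitted change, 202 of these windows rose and 1 fell by 8-fold or more. Rises were led by the locus at 79398001 to 79400000, from 0.0515 ± 0.0464 CPM with copper (2 reads in 3 libraries) to 1810 ± 414 without (SD, n = 3). Its ratio was 35200, with a counting interval of 7390 to 220000 (adjusted p = 4.91e-21, edgeR). The locus at 11530001 to 11532000 rose from 0.0515 ± 0.0464, again 2 reads, to 240 ± 31.4 (0.534 in the single crr1:CRR1 library), a ratio of 4670 with a counting interval of 1010 to 30200 (adjusted p = 5.95e-18, edgeR). Falls were led by the locus at 4460001 to 4463000, from 28.8 ± 6.75 to 4.33 ± 0.607, or 6.64-fold (adjusted p = 1.59e-09, edgeR). At 33583001 to 33586000 the level fell from 755 ± 167 to 195 ± 44.8, or 3.87-fold (adjusted p = 1.44e-12, edgeR). All 4 loci changed the same way in each of the 3 sequencing formats, which the naming rule required.

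The calls came from 76755 windows tested by edgeR's quasi-likelihood F test, of which 9232 had an unadjusted p under 0.05. The total of 1096 was 710 with DESeq2. It was 682 without the 33-nt library of either copper condition, and 690 and 695 without the 35-nt single-end library without and with copper.

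**Figure D1:**
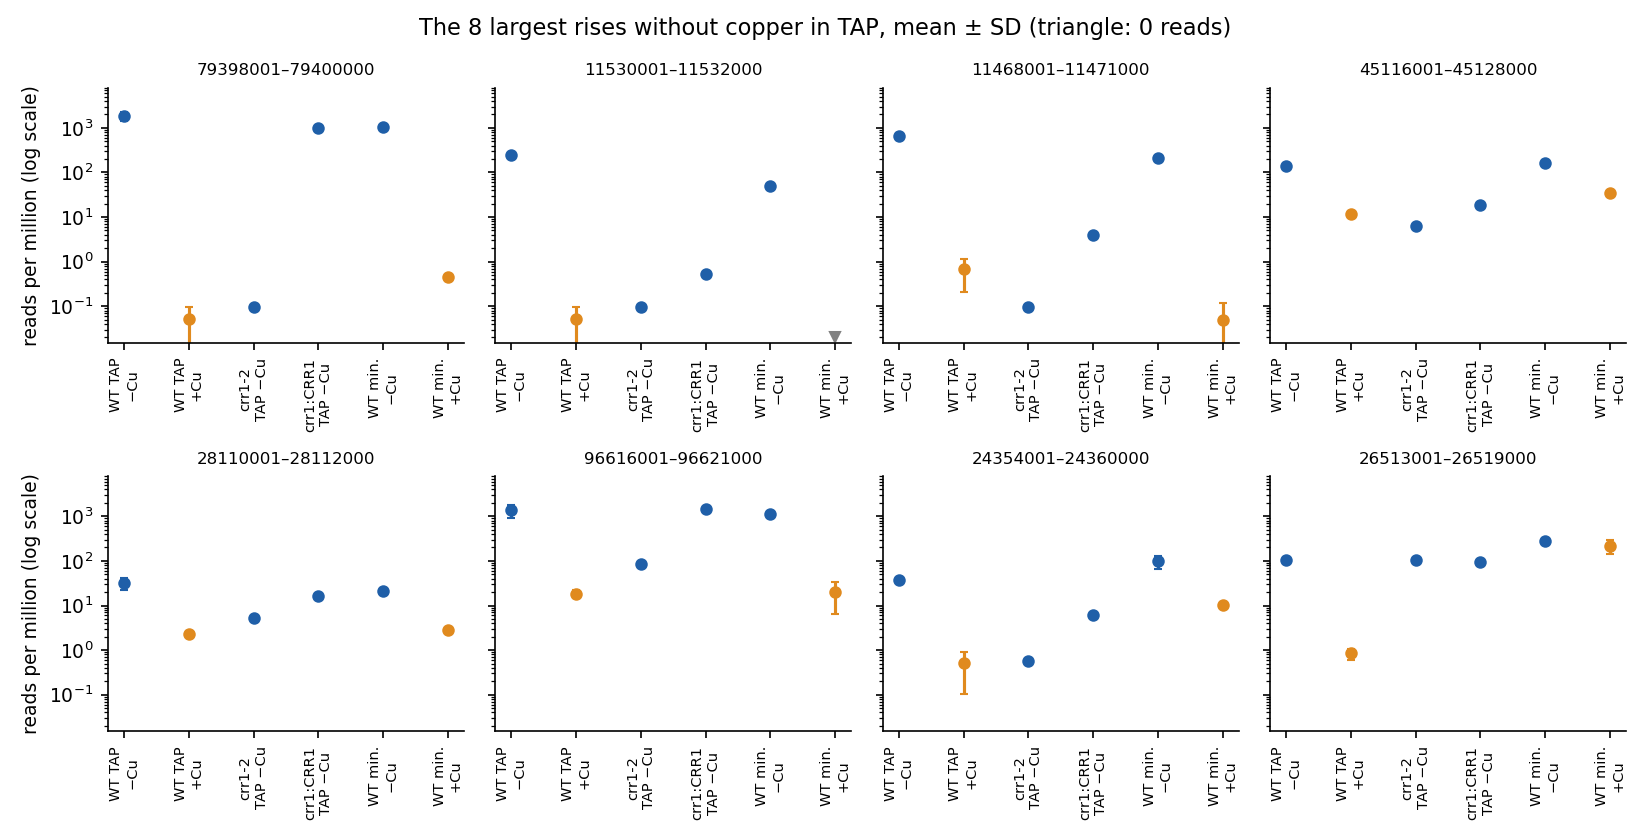
Levels at the 8 loci with the largest rises without copper in TAP, in CPM on a log axis, for the 6 groups (WT, wild type; min., minimal medium; blue, without copper; orange, with copper). Points are means, bars the SD over libraries where a group has more than 1 (the lower bar is shortened where the SD exceeds the mean, as a log axis has no 0), and the triangle marks 0 reads. At 79398001 the level was 1810 without and 0.0515 with copper, while at 26513001 minimal medium held 278 without and 215 with copper.

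The same question was put to cells grown without acetate. In minimal medium 840 windows in 270 loci were higher without copper and 98 windows in 71 loci were lower, with 202 rising and 3 falling by 8-fold or more. Rises were led by 38364001 to 38367000, from 0.492 ± 0.138 to 1190 ± 119 CPM (SD, n = 2), or 2410-fold (adjusted p = 2.38e-18, edgeR). In TAP it went from 17.2 ± 3.95 to 3180 ± 641 (n = 3). At 11468001 to 11471000 the level rose from 0.0492 ± 0.0695, a single read, to 210 ± 8.24, a ratio of 4260 with a counting interval of 763 to 168000 (adjusted p = 1.47e-15, edgeR). This locus stood at 3.89 in the single crr1:CRR1 library without copper in TAP, where wild type had 644 ± 109. The locus at 79398001, the first in TAP, rose here from 0.443 ± 0.071 to 1030 ± 8.14. Falls were led by 59369001 to 59373000, from 10.0 ± 6.37 to 1.96 ± 0.516, or 5.1-fold (adjusted p = 0.000951, edgeR), and by 101516001 to 101519000, from 7.29 ± 0.536 to 1.2 ± 0.77, or 6.06-fold (adjusted p = 0.000448, edgeR). The fall at 59369001 was no longer called without library 1 with copper (adjusted p = 0.184, edgeR, the highest over its alternatives, with 2.53e-05 the lowest), and DESeq2 gave it no adjusted p. The fall at 33583001 seen in TAP recurred, from 696 ± 55.8 to 142 ± 14.9, or 4.9-fold.

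Of 76755 windows tested, 8653 had an unadjusted p under 0.05. DESeq2 called 578 windows in place of 938. Leaving out library 2 without copper raised the count to 1856, and that library and its partner stood apart from each other in 683 windows when 1 was tested against the other.

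The responses in the 2 media shared many windows. Of the 972 windows that rose in TAP, 474 also rose in minimal medium, where 10.6 would be shared by independent lists (odds ratio 195, with a p too small for the software to represent, Fisher's exact test, two-sided). Counted by locus, 135 of the 346 rising TAP loci held a window that rose in minimal medium. The direction in minimal medium was upward for 93.1% of the rising TAP windows, with a median log2 change of 1.3 against 1.79 in TAP. It was downward for 75.8% of the falling TAP windows, with a median of -0.45 against -1.28. Of the 124 falling TAP windows, 12 also fell in minimal medium, against 0.158 for independent lists (odds ratio 95.2, p = 1.32e-19, adjusted 3.7e-19, Fisher's exact test, two-sided), but by locus only 5 of 82. Neighbouring windows of 1 transcript are not independent, so the p-values of these overlaps are too small. Across the 1544 windows called in either medium the log2 changes correlated at r = 0.67, and across all tested windows at 0.357. Both are across windows, which are not independent replicates. No library is shared by the 2 comparisons.

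**Figure D2:**
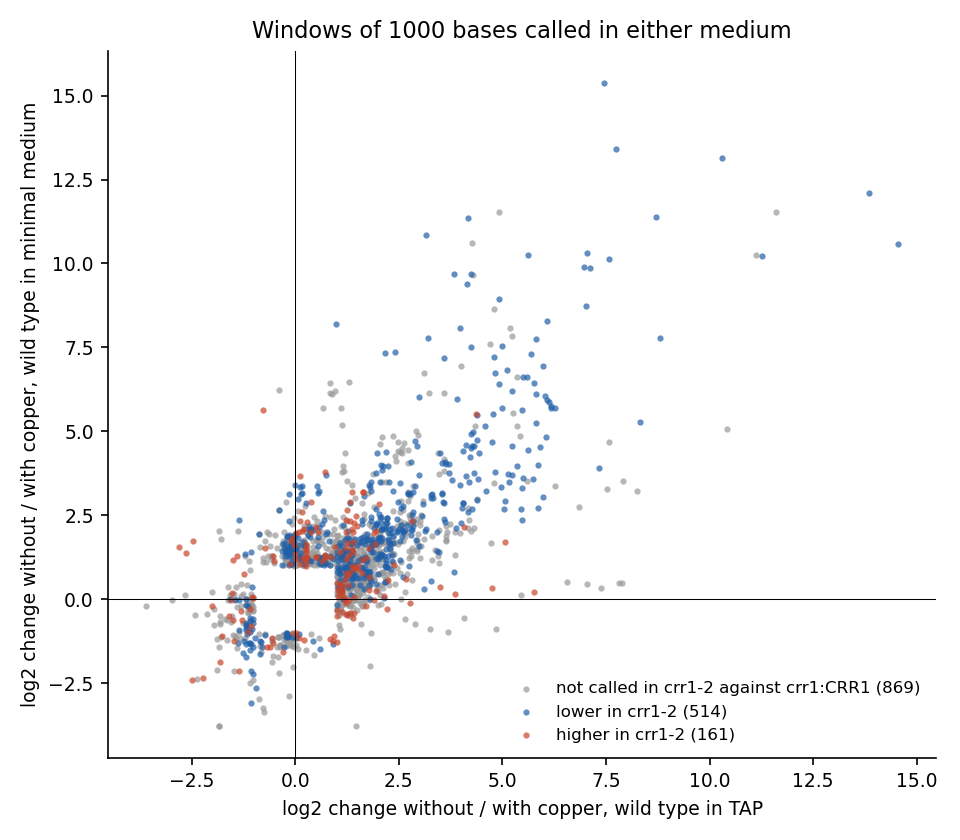
Log2 change without over with copper in TAP (x axis) and in minimal medium (y axis) for the 1544 windows of 1000 bases called in either medium, 1 point per window. Colours give the call between crr1-2 and crr1:CRR1 without copper. Of the 474 windows that rose in both media, 260 were lower in crr1-2. The correlation across the 1544 windows is 0.67, against 0.357 across all tested windows.

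Whether the size of the copper effect differed between media was tested directly as an interaction. It differed in 202 windows. The log2 change was higher in TAP in 69 windows of 39 loci and in minimal medium in 133 windows of 45 loci. In 105 of the 202 windows the changes had opposite signs in the 2 media, though only 4 were called in opposite directions, and 18 were called in neither medium. At 26513001 to 26519000 the wild type went from 0.84 ± 0.234 to 107 ± 12.8 CPM on copper deficiency in TAP, or 128-fold, while in minimal medium it stood at 215 ± 74.1 with copper and 278 ± 42.4 without (adjusted p of the difference = 4.65e-10, edgeR). The locus at 29085001 to 29086000 went from 0.553 ± 0.238 to 9.76 ± 4.86 in TAP, and in minimal medium from 1.28 ± 0.143 to 0.856 ± 0.387 (adjusted p of the difference = 2.11e-05, edgeR; DESeq2 gave none). In the other direction, 38364001 to 38367000 rose 2410-fold in minimal medium and 185-fold in TAP (adjusted p of the difference = 1.68e-06, edgeR). Next in this direction was 42748001 to 42749000, with a difference in log2 change of -7.69 (adjusted p = 0.0203, edgeR). It held 20.2 and 22.7 CPM in minimal medium without copper and 0 with copper, but was passed over for its level under 5 CPM in TAP. The locus at 42754001 to 42756000 rose 23.7-fold in minimal medium, from 6.75 ± 2.32 to 160 ± 25.3, and 3.93-fold in TAP, from 3.54 ± 0.76 to 13.9 ± 2.07 (adjusted p of the difference = 0.00193, edgeR). That last difference was not called when a 33-nt or a 35-nt single-end library was left out, with adjusted p from 0.0983 to 0.259 (edgeR); the lowest over its alternatives was 0.00115, with DESeq2. The locus at 4460001, which fell 6.64-fold in TAP, rose 2.96-fold in minimal medium, from 3.94 ± 0.267 to 11.7 ± 0.255.

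The interaction count is sensitive to single libraries. It was 58 to 94 when any 1 of the 6 TAP libraries was left out, 366 without library 1 and 645 without library 2 of minimal medium without copper. At an unadjusted p under 0.05 there were 5599 windows.

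The third comparison set crr1-2 against crr1:CRR1, both without copper, to find transcripts whose level depends on CRR1. By the same edgeR test, 4997 windows in 2380 loci were lower in crr1-2 and 4410 windows in 2391 loci were higher. By fitted change, 946 were lower and 423 higher by 8-fold or more. The locus at 79398001 was the most reduced: it had 1 read in crr1-2, or 0.0965 CPM, against 964 in crr1:CRR1, a ratio of 9990 with a counting interval of 1790 to 395000. At 44512001 to 44520000 the level was 7.05 in crr1-2 and 2460 in crr1:CRR1, or 349-fold lower. In the wild type that locus stood at 1030 ± 193 without and 53.6 ± 3.19 with copper in TAP (n = 3), and at 2110 ± 107 and 95.7 ± 17.3 in minimal medium (n = 2). At 33825001 to 33834000 crr1-2 had 716 and crr1:CRR1 6.1 CPM, 117-fold higher, with wild type between them at 88.7 ± 16.5. At 51954001 to 51964000 the levels were 1390 and 23.4, or 59.3-fold higher, with wild type at 393 ± 34.4. The locus at 33583001, which fell on copper deficiency in wild type, stood at 886 in crr1-2 and 171 in crr1:CRR1. Each strain has 1 library, so these differences have no replicate check and the calls rest on the spread of the other groups. DESeq2 called 3316 windows in place of 9407. The balance of directions followed the scaling: with RLE size factors 4906 windows were higher and 4604 lower, and with DESeq2 1878 and 1438.

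The overlap of these calls with the copper response asked which part of it needs CRR1. Of the 972 windows that rose without copper in TAP, 345 were lower in crr1-2 than in crr1:CRR1, or 35.5%, against 63.3 windows for independent lists (odds ratio 8.41, p = 4.28e-159, adjusted 1.5e-158, Fisher's exact test, two-sided). As above, neighbouring windows make such p-values too small. In crr1:CRR1 itself the median log2 ratio to wild type was -0.38 in windows rising in TAP and -0.33 in those rising in minimal medium. The first shares wild-type libraries with the calls of the rise. Windows low in both strains can escape the count, so the share does not measure the whole part of the response that needs CRR1. Counted by locus, 118 of 346 held such a window. For rises in minimal medium it was 373 of 840 windows, or 44.4%, against 54.7. Among windows that rose in both media 260 of 474 were lower in crr1-2, and among those that rose in TAP without a call in minimal medium 85 of 498; the difference between these shares was not tested. By size of the response, 22.4% of windows rising 2- to 4-fold in TAP were lower in crr1-2, and 66.9% of those rising 16-fold or more. In minimal medium the share went from 32.8% to 72% at 8- to 16-fold and was 64.6% at 16-fold or more. These shares count calls, and in simulated data 8.16% of 2-fold and 64.3% of 4-fold changes between the strains were recovered. Few windows were changed there, which makes the adjusted p stricter, so these rates are not those of the real calls. The 2-fold changes also lay at the limit of the minimum fold, which alone keeps part of them from being called. A rise of the share with size does not separate CRR1 dependence from power. The median log2 ratio of crr1-2 to crr1:CRR1, which counts no calls, went from -0.36 at 2- to 4-fold to -3.43 at 16-fold or more in TAP. In minimal medium it went from -0.77 to -3.19. Whether it keeps pace with the rise was not tested. Windows that rose without copper in TAP and were higher in crr1-2 numbered 79, against 55.8 for independent lists (odds ratio 1.46). Of the 124 windows that fell in TAP, 24 were higher in crr1-2 (7.12 for independent lists, odds ratio 3.95) and 36 were lower (8.07, odds ratio 5.91). Windows called for copper in TAP were thus more often called between the strains in either direction. An excess over independent lists alone therefore does not show dependence on CRR1. With DESeq2 calls the overlap was 220 of 664 windows, against 12.4. The copper comparisons and that of crr1-2 with crr1:CRR1 share no library.

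**Figure D3:**
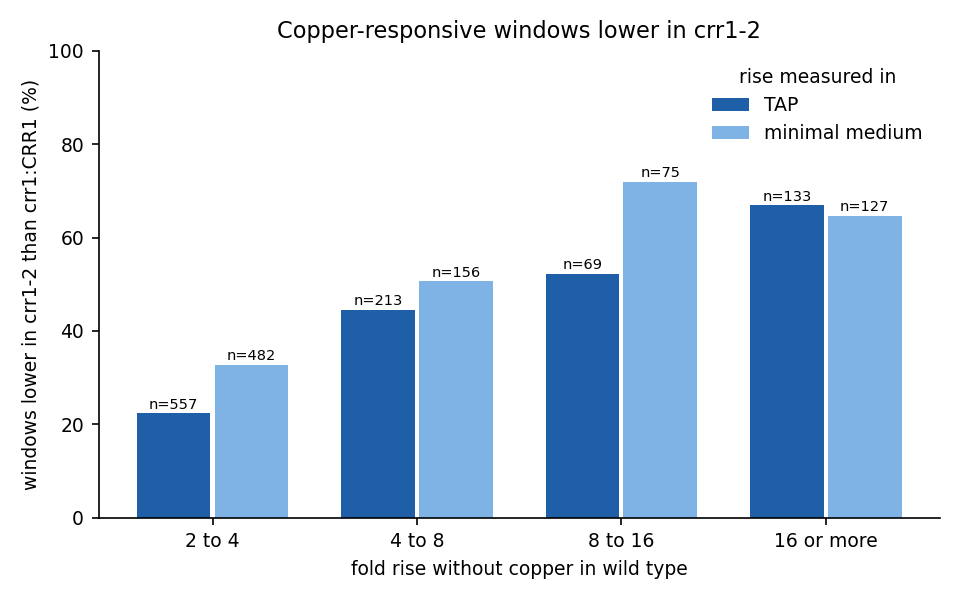
Share of windows lower in crr1-2 than in crr1:CRR1 (y axis, percent) by the fold rise without copper in wild type (x axis), for rises measured in TAP and in minimal medium; n is the number of windows behind each bar. The TAP share goes from 22.4% at 2- to 4-fold to 66.9% at 16-fold or more, and the minimal-medium share from 32.8% through 50.6% and 72% to 64.6%.

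A region of at least 15 kb had almost no reads in crr1-2. From 91278001 to 91293000 crr1-2 held 1 read, or 0.0965 CPM, and crr1:CRR1 1492 reads, or 114 CPM. Wild type stood at 96.6 without and 91.9 with copper in TAP, and at 99.5 and 132 in minimal medium, with single libraries between 82.7 and 137. To the right, from 91293001 to 91305000, crr1-2 held 1 further read, where 74.7 were expected and crr1:CRR1 held 102. The bounds of this region were set by a scan chosen after its values were seen.

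**Figure D4:**
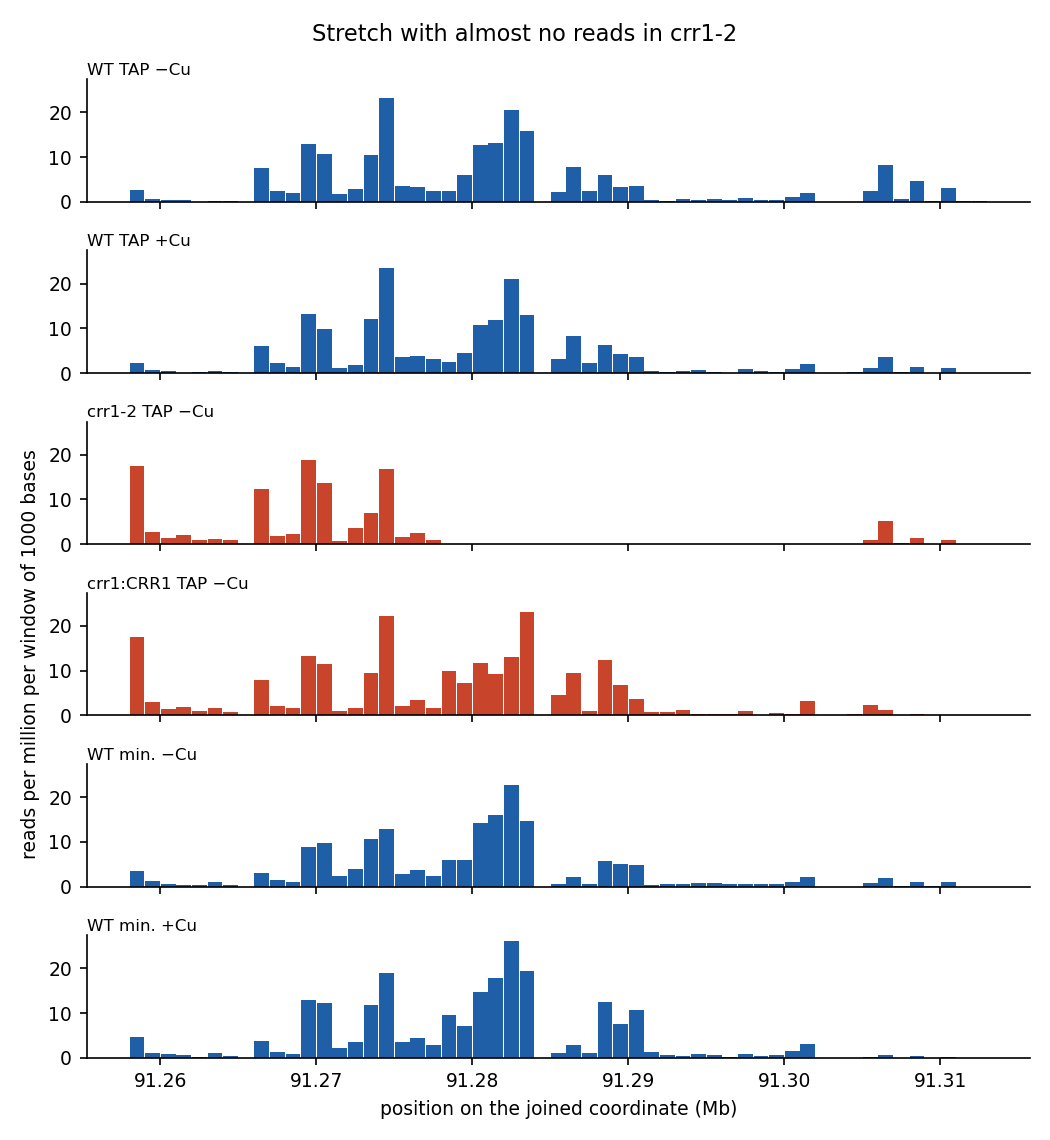
CPM per window of 1000 bases (y axis) along the joined coordinate in Mb (x axis) around 91278001 to 91293000, 1 panel per group, bars giving the mean of its libraries (WT, wild type; min., minimal medium; blue, wild type; red, the other strains). The crr1-2 panel is empty across the stretch, with 1 read, where crr1:CRR1 held 1492.

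Against wild type without copper, crr1-2 differed in 22412 windows, 11313 higher and 11099 lower. The locus at 79398001 again led the falls, with a ratio of 18800 (counting interval 3130 to 690000). The locus at 11468001 had 1 read in crr1-2 against 644 ± 109 CPM in wild type, a ratio of 6670 (counting interval 1150 to 253000). Higher in crr1-2 were 38422001 to 38427000, at 220 against 35.6 ± 7.12, or 6.2-fold, and 53278001 to 53283000, at 154 against 7.11 ± 1.15, or 21.7-fold. The complemented strain also differed from wild type, in 17681 windows, 9250 higher and 8431 lower. It held 140 CPM at 38422001, 3.93-fold more than wild type. At 109688001 to 109690000 it held 80.9 where wild type without copper had 0 reads, at least 860-fold higher. Lower in crr1:CRR1 were 38720001 to 38727000, 9.29-fold, and 30493001 to 30518000, 69.3-fold, the latter at 2.75 CPM against 190 ± 2.16 in wild type and 1.83 in crr1-2. Both strains differed from wild type in the same direction in 10106 windows. The correlation of the 2 sets of log2 changes was 0.654 with a covariance of 1.365. In 5 draws that simulated all 12 libraries from 1 mean per window, the mean values were 0.388 and 0.093. Those draws hold no difference between groups or formats, so they do not show the whole part due to shared libraries. The 3 wild-type libraries are shared by both comparisons and are too few to be divided between them.

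The wild-type libraries without copper were themselves 2-fold apart between formats in up to 6060 of 25729 windows with at least 5 CPM in the higher library, the 33-nt against the 35-nt paired-end library. Counts against wild type fell to 12367 for crr1-2 and 7740 for crr1:CRR1 without the 35-nt single-end wild-type library, the only one in the strains' format, and to 12446 and 8377 with DESeq2. Without that library the window leading 79398001 went from a log2 change of -16.04 to -13.16 between crr1-2 and wild type and lost its call. Its other alternatives gave an adjusted p of 2.3e-17 to 1.34e-10 (edgeR). Without that library the strains' format is tied to wild type only through copper-sufficient libraries, which held 2 reads at this locus. The contrast there is therefore poorly determined. The cause of the lost call was not tested further. With RLE size factors the crr1-2 windows divided into 12451 higher and 9973 lower.

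Minimal medium was compared with TAP in copper-sufficient wild type, where medium and sequencing format cannot be told apart. In minimal medium 6007 windows were higher and 5156 lower by the edgeR test without a format term. The locus at 53278001 stood at 308 ± 51.7 (n = 2) against 9.31 ± 2.49 (n = 3), or 33.1-fold higher, and 72311001 to 72316000 at 111 ± 49.1 against 0.225 ± 0.149, or 495-fold. At 61616001 to 61619000 the level was 0.0987 ± 0.14 (2 reads) against 19.5 ± 4.26, a ratio of 197 with a counting interval of 50.5 to 1520. At 114003001 to 114005000 it was 0.0494 ± 0.0698 (1 read) against 16.5 ± 3.51, a ratio of 334 with a counting interval of 55.9 to 12400. The count of 11163 fell to 4545 and 3910 when the first or the second minimal-medium library with copper was left out.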

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

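The test of single samples within a format was set up after the values per sample had been seen; the other tests in this part were planned. A single sample stood apart within its format, though not within its whole group. Among the 4 samples of 33 nt of wild type in TAP without copper, sample 9 of the labels had 77.87% of its reads aligned over the full length, where the other 3 had 83.31 to 83.39%, a gap past Dixon's 95% criterion (Q = 0.986). Among all 8 samples of that group the same value had a Q of 0.41, short of the criterion. With 18 sets and measures tested and 1 past the criterion, chance gives about 1 in 20. The other result is a difference between groups: the copper effect differed between TAP and minimal medium in 202 windows by the interaction term, a count that was 58 to 94 when any 1 of the TAP libraries was left out and 366 or 645 when library 1 or 2 of minimal medium without copper was left out.

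The 1096 windows called between wild type without and with copper in TAP were set against the other splits of the 6 libraries into 3 and 3. There are 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many as 1096 windows, and the highest of the others gave 0. The label numbers pair the libraries by format, and the 3 other splits that part every pair also gave 0.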

How the results depend on the processing

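Windows of 500 and 5000 bases, single counting of positions, full-length alignments only and leaving out the 33-nt libraries were chosen after the data were seen, as were several alternatives for the overlap and the medium comparison. Counts follow the number of windows tested: with 5000-base windows they were 263 for copper in TAP, 287 in minimal medium, 3017 for crr1-2 against crr1:CRR1, 5546 and 3759 for crr1-2 and crr1:CRR1 against wild type, 72 for the difference between media, 3427 for medium and 107 for the overlap. With 500-base windows they rose to 1704 for copper in TAP, 34441 and 30126 for the 2 strains against wild type and 530 for the overlap. DESeq2 called fewer in most: 710, 578, 3316, 12446 and 8377 in the order above, and 220 in the overlap; the cause was not tested. Without a minimum fold, copper in TAP gave 1700. Without the 33-nt libraries, which leaves fewer samples, copper in TAP gave 671 and the difference between media 54. Leaving out 1 library at a time gave 682 to 859 for copper in TAP, 700 to 1856 in minimal medium, 12367 to 21591 for crr1-2 and 7740 to 16856 for crr1:CRR1 against wild type, 58 to 645 for the difference between media, 3910 to 9970 for medium and 275 to 310 for the overlap. Where leaving out a library left 1 in a group, it was assumed to vary like the other groups. All other alternatives run kept each count within 1.5 times, though RLE size factors turned the balance of crr1-2 against crr1:CRR1 to 4906 higher and 4604 lower. Of 344 recalculations of the loci named by the rule, 335 kept direction and call, 9 lost the call and 0 reversed. Depth limits ratios against groups with 1 to 3 reads, as the interval of 1790 to 395000 around 9990 shows.

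With the label numbers as a replicate block, copper in TAP gave 1096 windows, as the block equals the format term there. In minimal medium, where the numbers did not pair the libraries (correlation -0.021), it gave 1103. The lone crr1-2 and crr1:CRR1 libraries cannot be blocked or left out. Fits of 1 single-end format alone, or of only the compared groups for the strains with the format term, could not be run, having no residual degrees of freedom. The strains with 35-nt wild type alone were not fitted. Gene lists were not run, as positions carry no gene names. Overlap with windows lower in crr1-2 than in wild type was 511, against 141 for independent lists; the 2 comparisons share 3 wild-type libraries, so part of it may come from them. Simulated unchanged groups gave 0, but with 0 windows called in either list this says nothing of the overlap. Over all tested windows the log2 changes had a correlation of -0.184 and a covariance of -0.159, against -0.302 and -0.0476 for the simulated groups. The simulated groups hold no difference between formats.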

Other observations

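The tests of reads, copper response and complementation at the silent stretch, the counts of loci and libraries in the crr1:CRR1 strain, the comparison of single wild-type libraries with their own group and that of libraries of 1 format were chosen only after the result was seen. So were the settings of the scan for stretches, the set of copper loci used for complementation, and the limit of 1/32 of wild type.

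Stretches nearly silent in both crr1-2 and crr1:CRR1 numbered 3. From 30494001 to 30515000 the strains held 9 reads where 3792.2 were expected from the wild-type libraries, and from 38606001 to 38645000 they held 23 where 3925 were expected. From 61740001 to 61754000 they held 145 where 6138.9 were expected. Wild type had reads in every condition at all 3, but at the last it stood at 435 and 422 CPM without and with copper in TAP and at 7.1 and 5.81 in minimal medium. At the first it stood at 156 without and 170 with copper in TAP, and at 152 and 172 in minimal medium. In the other direction the 10 wild-type libraries together were nearly silent in 3 stretches where the strains had reads. From 60200001 to 60210000 they held 153 reads where 9919.6 were expected from the strains, from 88032001 to 88044000 they held 13 where 1916 were expected, and from 104460001 to 104473000 they held 240 where 10196.5 were expected. The scan took at least 10 expressed windows in a row with at most 5% of the expected reads. It also finds regulated transcripts, such as 48645001 to 48655000, which held 2 reads in minimal medium with copper and 1038 without.

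In the stretch from 91278001 to 91293000, silent in crr1-2 alone, that library had 1 read where 1066.9 were expected, as the scan required few reads. The 20 windows to its left, outside that rule, held 1128 reads where 893.6 were expected, which argues against too few reads in the crr1-2 library. To its right the near silence went on to 91305000, with 1 read where 74.7 were expected, and the next 20 windows held 170 where 226.5 were expected. The log2 ratio of the stretch without over with copper in wild type in TAP was 0.07, which argues against transcripts that respond to copper through CRR1. In crr1:CRR1 the stretch at 91278001 stood at 1.18 times the wild-type level. This leaves standing the hypothesis that DNA was missing or not transcribed in crr1-2 and put back in crr1:CRR1. That stretch may thus include the mutated gene. No gene position was used, each strain has 1 library, and the hypothesis was formed on the same data, so it stays open.

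Of 42 loci whose most changed window rose at least 8-fold in minimal medium, and which as whole loci rose at least 4-fold in TAP, 31 lay at least 4-fold below wild type in crr1-2, and in crr1:CRR1 their median log2 ratio to wild type was -0.72. By the same 4-fold limit 5 of them were low in crr1:CRR1 too: 11468001 and 11530001, at 3.89 and 0.534 CPM against 644 and 240, and, with no explanation tested, 45116001, 24354001 and 58433001, at 18.6, 6.26 and 32.5 against 141, 38 and 152. For the first 2, the only ones of the 31 below 1/32 of wild type, weak complementation at all loci is argued against, since 74.2% of the 31 reached at least 0.5 times wild type. The windows around these 2, summed over both sides, held at least 92.4% of the expected reads in crr1:CRR1. This argues against a missing or unmapped region that covers most of those windows. A gap reaching a shorter way past a locus stays open, since such a sum can hide it. Around the stretch at 91278001 the same sum in crr1-2 held 1220 reads where 1110 were expected, although near silence ran on to its right. A change of this crr1:CRR1 culture and a change of the strain at these 2 loci cannot be told apart with 1 library. The set does not hold all such loci. Outside it, 26788001 to 26798000 stood at 1.37 CPM in crr1:CRR1 and 12.1 in crr1-2, against 187 ± 35.4 in wild type without copper in TAP. In wild type that locus rose 7.24-fold without copper in TAP and 5.21-fold in minimal medium.

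Between crr1:CRR1 and wild type 17681 windows were called, against 1096 for copper in TAP. To gauge the noise of a lone library, single wild-type libraries were set against the rest of their own group, after the format term. In TAP each gave 0 windows, but there the format term also takes up what a library shares with its same-format partner. In minimal medium, which has 1 format and no such term, each library gave 683 without copper and 0 with copper. The crr1:CRR1 library differs from these in format and medium, so noise of that library is not excluded. Sequencing format as labelled is argued against, since over all tested windows with at least 5 CPM in the higher library the 35-nt single-end libraries of crr1:CRR1 and wild type without copper were 2-fold apart in 8618, while wild-type TAP libraries of 1 format, without against with copper, were so in 651 to 1157. The crr1:CRR1 library was closer to the 33-nt wild-type library without copper, at 6206 windows, which is near the 6060 between the 33-nt and 35-nt paired-end wild-type libraries of that group, so labelled format does not make a matched pair. Strain background, culture and library preparation cannot be told apart, because there is only 1 library of the crr1:CRR1 strain.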
